A study of Pardosa pseudoannulata with 6 samples.

How the data were processed

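The samples were 6 RNA sequencing libraries of Pardosa pseudoannulata, a wolf spider of rice fields. Each library was made from material labelled as an individual. If this means a whole animal, which the labels do not spell out, the values average over all organs. All animals had received cadmium and a microinjection of double-stranded RNA, which triggers RNA interference. In 3 libraries the injected RNA was a negative control (dsNC) and in 3 it was directed at the F-actin gene (dsFactin). Groups were taken from the sample titles. RNA was extracted with an RNeasy kit and libraries were made with a SMARTER mRNA kit, per the labels' protocols. Beyond the word individual, no label says that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

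The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to depth), rounded to 2 decimals, with 1 column per library and 75542 genes. The aligner, counter and assembler are not given in the sources used here. The submitters' processing notes name the genome build mm10, a mouse build. The deposited FPKM table does not carry mouse genes: its genes are numbered clusters without coordinates, each with a length and, for 24833 of them, a best protein hit. No positions in a genome are therefore given, and gene names below are those of the best hits in the table. Related transcripts such as the actins, hemocyanins and spidroins share sequence, and how reads were divided among them is not given in the sources used here, so values of single members are uncertain.

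Counts of fragments were not given, so depth was read from the steps between low FPKM values, which scale with gene length less a constant. With 99.5 to 99.8% of low values within 0.1 of a whole number of fragments, the recovered depth was 15.8, 16.3 and 17.6 M fragments (M, 1e6) in dsNC replicates 1 to 3 and 18.0, 16.6 and 16.1 M in dsFactin replicates 1 to 3. At these depths 3 fragments in a gene of 1000 bases equal 0.232 to 0.276 FPKM. An FPKM of 0 is reported as listed at 0. The 10 most abundant genes held 10.7 to 13.8% of each library's FPKM.

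Genes with at least 0.5 FPKM in at least 3 libraries were tested, 53182 in all. Values were analysed as log2(FPKM + 1), so fold changes understate the change of genes near or below 1 FPKM. Groups were compared with limma 3.58.1 in R 4.3.3, two-sided, with an intensity trend in the empirical Bayes step and Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. Count models were not used as the main test, since FPKM values are not counts. Tested on simulated data for this comparison with the spreads of the 53182 real genes, the fit called 4% of 100 genes changed 2-fold and 73% of 100 genes changed 8-fold, with 4 false calls. The changed genes were drawn from those with a mean of at least 5 FPKM, so these shares do not cover genes at lower levels. Exact permutation tests of single values were two-sided and could not give a p below 0.1 with 3 libraries against 3.

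The design, the alternatives and 26 gene lists were fixed before the data were examined. The lists were drawn by words in the best-hit descriptions and covered actins, actin-binding proteins, Hippo signalling, muscle, cuticle and chitin, metal binding, heat shock proteins and chaperones, antioxidant enzymes, detoxification, immunity, hemocyanin, yolk and egg, germ line, testis and sperm, venom, silk, digestive enzymes, nervous system, apoptosis, cell cycle, cytosolic ribosomal proteins, oxidative phosphorylation, proteasome, RNA interference, moulting hormones, and matrix and adhesion. Several lists mark organs or cell types that a whole animal holds in differing amounts. Lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 26 lists, then with an estimated correlation and with fry. Words can take in unrelated genes: 73 of 153 members of the actin-binding list entered only because "formin" is part of "forming". Gene Ontology and Pfam terms of 5 to 500 genes were tested with Fisher's exact test against the 17294 tested genes that carry any term.

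Genes named below followed a rule also fixed beforehand. It took every actin with a mean of at least 1 FPKM and, among named genes that passed with a mean of at least 1 FPKM and no overlap between groups, the 10 largest rises and 10 largest falls. It further took up to 2 positive and 2 negative members per list by adjusted p, the whole Hippo list as counts, and the 3 largest rises and falls among unnamed genes. This gave 128 genes, not all of which are named below, so the members named for a list need not show both directions. Other genes are marked as chosen after their values were seen. The alternatives were pseudocounts of 0.1 and 0.01, no filter, a filter on a mean of at least 5 FPKM, rescaling by median ratios, rescaling to an equal sum, quantile normalization, no trend, array weights, the replicate number as a block, an added 2-fold limit, and leaving out each library. These were fixed for the count of changed genes, and part of them for the actins and the lists. Added after seeing the data were the rest of them for the actins and lists, limma's voom on the recovered fragments, removal of genes whose best hit was a Drosophila species, the filter taken again after each library was left out, and the actin-binding list without the words named above. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.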

Results

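The series asked which transcripts follow the knockdown of F-actin in cadmium-exposed wolf spiders, with the Hippo signalling pathway as its candidate target. The data were FPKM values of 75542 assembled genes in 3 control libraries (dsNC) and 3 knockdown libraries (dsFactin), all from cadmium-treated individuals. Depth was 16.6 ± 0.929 M fragments in dsNC and 16.9 ± 0.985 M in dsFactin (SD, n = 3, exact permutation p = 0.6). Genes above 0 numbered 57714, 60864 and 61503 in dsNC replicates 1 to 3 and 54264, 55781 and 47167 in dsFactin replicates 1 to 3.

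Actin transcripts, the family of the injected double-stranded RNA, did not move as one. Actin-87E (Cluster-8110.35523) was at 880, 1119 and 1057 FPKM in dsNC and 338, 397 and 558 FPKM in dsFactin, a log2 difference of -1.26 ± 0.21 (SE, adjusted p = 0.0675, limma). The actin cytoplasmic A3a-like transcript (Cluster-8110.34823), the most abundant of the family in dsNC, was at 4443, 5949 and 5426 FPKM in dsNC and 1906, 2321 and 3221 FPKM in dsFactin, a log2 difference of -1.11 ± 0.24 (adjusted p = 0.0911). A partial beta-actin hit (Cluster-8110.53255) differed by -1.13 ± 0.44 (adjusted p = 0.233) and an actin clone 403 transcript (Cluster-8110.34480) by -0.31 ± 0.17 (adjusted p = 0.375), the last turning positive after median-ratio rescaling. Further abundant actins were at slightly higher values in dsFactin: Cluster-8110.34975 at 1733 ± 61.0 and 1932 ± 153 FPKM, Cluster-8110.34334 at 1245 ± 36.1 and 1385 ± 150 FPKM, and Cluster-8110.34222 at 306 ± 10.3 and 340 ± 15.2 FPKM (dsNC and dsFactin, SD, n = 3).

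Smaller members were at low values: an actin (Cluster-8110.35699) at 12.4 ± 1.68 and 7.89 ± 2.55 FPKM, Actin-2 (Cluster-8110.23246) at 5.63 ± 0.631 and 5.15 ± 1.26 FPKM, and actin-85C-like (Cluster-8110.4076) at 1.34 ± 0.798 and 0.880 ± 0.816 FPKM (dsNC and dsFactin, SD, n = 3). The list also held 3 genes whose products act on actin, a methionine sulfoxide oxidase (Cluster-8110.34018) at -0.55 ± 0.18, an actin-histidine methyltransferase (Cluster-8110.42116) at -0.14 ± 0.18 and the UPF0692 protein C19orf54 homolog (Cluster-8110.22599) at -0.20 ± 0.25 on the log2 scale (SE). Actin-2 and the last 2 of these turned positive after median-ratio rescaling and with quantile normalization. In limma, 0 of the 13 actin-list genes tested passed over all genes, 5 had an unadjusted p under 0.05, and 0 rose and 2 fell adjusted over the list alone. With camera the list had an adjusted p = 0.381 (adjusted p = 0.791 with an estimated correlation). All 3 dsFactin libraries lay below all 3 dsNC libraries for 5 of the 13 and above for 2, where chance gives 5% per direction. Of all 53182 tested genes, 21.5% lay below and 5.98% above, and 10270 had an unadjusted p under 0.05 in limma. Summed FPKM of the 13 was 13966 ± 993 in dsNC and 10077 ± 1645 in dsFactin (SD, n = 3). The log2 difference was -0.48 at an exact permutation p of 0.1, the smallest possible, and -0.15 at an exact p of 0.5 after median-ratio rescaling. Actin-87E and the A3a-like transcript passed with a filter on mean FPKM of at least 5 and with voom, and 1 of the family passed with array weights, settings applied to actins after seeing the data. The labels do not say which of these transcripts the injected RNA matched.

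**Figure D1:**
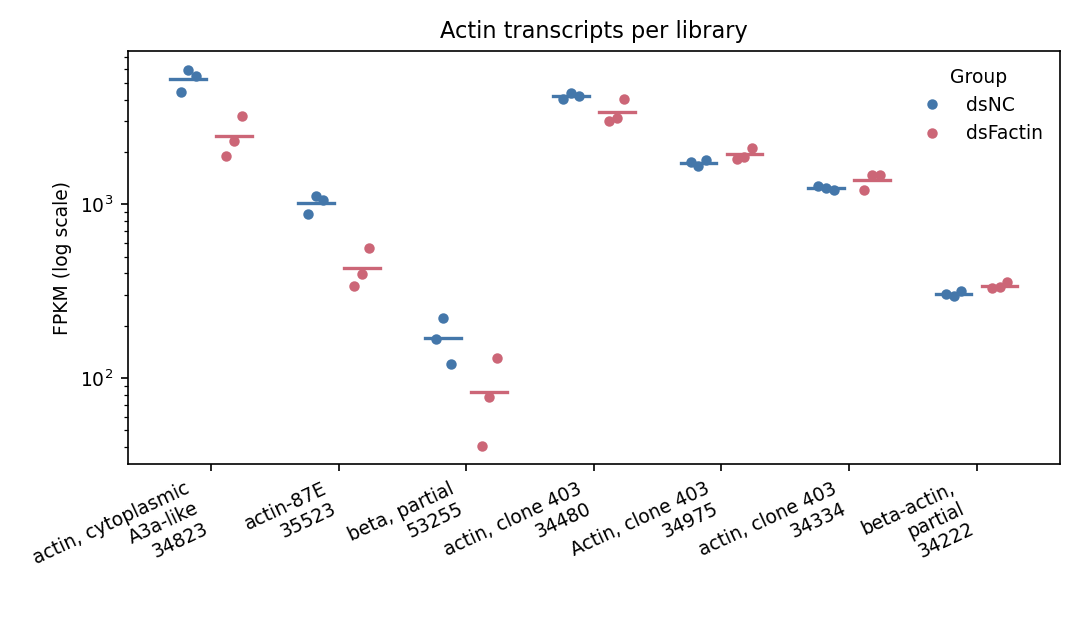
FPKM of 7 abundant actin transcripts (log axis) in each library, with dsNC in blue and dsFactin in red, points for libraries and lines for group means. The A3a-like transcript, actin-87E and, by a small margin, clone 403 transcript Cluster-8110.34480 were lower in all 3 dsFactin libraries than in any dsNC library at the deposited scaling, the last turning positive after median-ratio rescaling.

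Over all genes, 264 of 53182 passed in limma, 41 higher and 223 lower in dsFactin, and 105 of them carried a name. The largest rise was vitellogenin-1 (Cluster-8110.3985), an egg yolk precursor, at 0.290, 0.320 and 0.180 FPKM in dsNC and 809, 507 and 227 FPKM in dsFactin (log2 8.49 ± 0.44, adjusted p = 0.00209). An apolipophorins-like transcript (Cluster-8110.44450), of the lipid carriers of haemolymph, rose from a mean of 0.787 FPKM to 209 FPKM (log2 6.65 ± 0.46, SE, adjusted p = 0.00634). Other lipid carrier hits also rose: apolipoprotein B-100 (Cluster-8110.24455, log2 1.28 and Cluster-8110.39310, log2 1.22) and apolipophorin (Cluster-8110.35645, log2 1.17). Best hits of the last 2 are named as partial or a fragment, and whether these clusters are pieces of the same gene was not tested. The list of 10 largest rises was completed by a gene whose best hit is a nascent polypeptide-associated complex subunit (Cluster-8110.50450, log2 3.90), a U3-aranetoxin (Cluster-8110.16513, log2 2.42), papilin (Cluster-8110.39942, log2 1.44), cytochrome P450 4C1 (Cluster-8110.37598, log2 1.31) and acetylcholine-binding protein 5 (Cluster-8110.32505, log2 1.16).

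Among named genes the 10 largest falls included 5 cuticle protein hits. A rigid cuticular protein 15.7-like transcript (Cluster-8110.32557) was at 153, 185 and 177 FPKM in dsNC and listed at 0 in all 3 dsFactin libraries (adjusted p = 4.5e-05). Cuticle protein 16.8 transcripts (Cluster-8110.34146, log2 -6.38 and Cluster-8110.38329, log2 -5.44), pupal cuticle protein Edg-91-like (Cluster-8110.34768, log2 -6.10) and cuticle protein 10.9-like (Cluster-8110.28959, log2 -5.41) fell to means of 0.127 to 0.370 FPKM. Also among the 10 were hits to chaplin-C (Cluster-8110.28066, log2 -7.33), histidine-rich glycoprotein (Cluster-8110.36141, log2 -6.86), a SlyD-like isomerase (Cluster-8110.31600, log2 -6.78), prisilkin-39 (Cluster-8110.33327, log2 -5.66) and keratin 9 (Cluster-8110.33179, log2 -5.58). Unnamed genes moved as far, with Cluster-8110.33604 at 554 ± 134 FPKM in dsNC and 0.227 ± 0.200 FPKM in dsFactin (SD, n = 3), Cluster-8110.33346 at 353 ± 87.9 FPKM in dsNC and listed at 0 in dsFactin, and Cluster-8110.34197 differing by a log2 of -7.70 ± 0.32 (SE). Cluster-8110.14536 rose from 0.603 ± 0.653 to 53.0 ± 17.3 FPKM, while Cluster-8110.53496 and Cluster-8110.12644 were listed at 0 in dsNC and averaged 5.75 and 5.58 FPKM in dsFactin. Of the lower genes, 72 were listed at 0 in all 3 dsFactin libraries, and 11 of the higher genes were listed at 0 in all 3 dsNC libraries.

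In all 264 genes the groups did not overlap. An unadjusted p under 0.05 in limma was reached by 10270 of the 53182 tested genes, and 1162 passed with voom. Counts of this kind within lists are to be read beside these shares. Over all tested genes, dsFactin lay wholly below dsNC in 21.5% and wholly above in 5.98%, where chance gives 5% each. The median log2 difference over all genes was -0.27, -0.09 after median-ratio rescaling and 0.01 after quantile normalization. Medians of the lists that passed camera are therefore also given relative to all genes, and those of other lists are to be read beside -0.27. By mean level it was -0.25 under 1 FPKM, -0.36 from 1 to 5 FPKM and 0.09 over 50 FPKM, genes with a Drosophila best hit left out. The higher share of the calls was 15.5%, 27.6% with quantile normalization (67 higher and 176 lower) and 31.5% at a mean of at least 5 FPKM. It was 5.19 to 6.67% with a dsNC library left out and 5.88% with the replicate block. The count changed with the libraries used. It was 45, 33 and 77 without dsNC replicates 1, 2 and 3, and 58, 1297 and 105 without dsFactin replicates 1, 2 and 3. Only leaving out dsFactin replicate 2 raised it. All 264 genes kept their sign in each of these fits, which was fixed beforehand because their groups did not overlap.

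**Figure D2:**
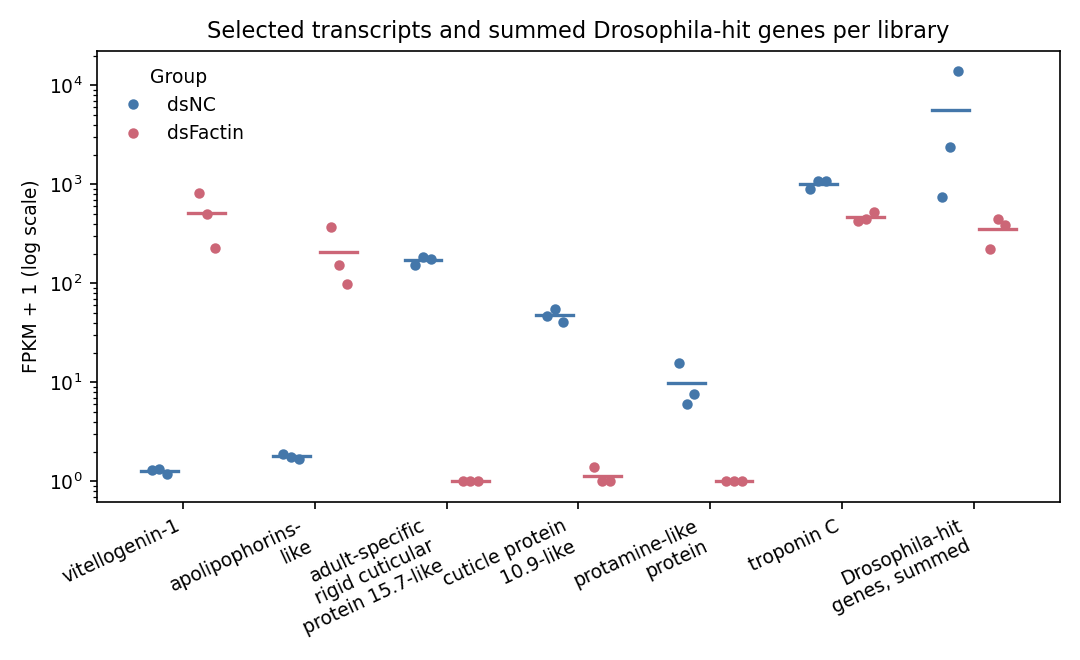
FPKM + 1 (log axis) of 6 transcripts and of the summed genes with a Drosophila best hit in each library, with dsNC in blue, dsFactin in red, points for libraries and lines for group means. Vitellogenin-1 and apolipophorins-like lay above 90 FPKM in dsFactin only, and the cuticle and protamine-like transcripts near 0 in dsFactin.

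Cuticle genes were lower in dsFactin. Of 239 tested members of the cuticle and chitin list, 0 rose and 23 fell over all genes, and 8 rose and 61 fell adjusted over the list alone. The list median was -1.16, or -0.89 relative to all genes (camera adjusted p = 0.000199, adjusted p = 0.324 with an estimated correlation). Cuticle protein 14-like (Cluster-8110.33293) differed by a log2 of -3.65 ± 0.45 (SE) from a mean of 873 FPKM, and adult-specific rigid cuticular protein 12.6 (Cluster-8110.36127) from 720 ± 138 to 94.2 ± 41.6 FPKM, both chosen after their values were seen. Members did not all go one way: 57 were positive, among them chitin deacetylase 1-like transcripts, enzymes that modify chitin, at log2 1.77 (Cluster-8110.25825, adjusted p = 0.0610) and 1.84 (Cluster-8110.31366, adjusted p = 0.0640). A more abundant chitin deacetylase 1-like transcript (Cluster-8110.35395, chosen after its values were seen) fell from 333 ± 19.5 to 142 ± 15.3 FPKM. Summed cuticle FPKM overlapped between groups, at 42953 ± 3442 in dsNC and 34508 ± 10514 in dsFactin (SD, n = 3, exact permutation p = 0.3).

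Muscle genes were lower as a group. Of 166 members of the muscle list, 1 rose and 4 fell over all genes, and 2 rose and 59 fell adjusted over the list alone. The genes that fell were titin-like (Cluster-8110.32220, 26.4 ± 3.10 to 4.62 ± 0.937 FPKM), a sarcomere scaffold, ryanodine receptor-like (Cluster-8110.34252, 30.9 ± 3.40 to 12.6 ± 1.95 FPKM), a calcium release channel, and troponin T (Cluster-8110.35305, 1277 ± 148 to 575 ± 77.0 FPKM) and troponin C (Cluster-8110.35522, 1014 ± 107 to 466 ± 54.6 FPKM), calcium switches of contraction (SD, n = 3, the troponins named after their values were seen). The 1 that rose was the nascent polypeptide-associated complex hit named above, which entered by the words muscle-specific and is not a contractile protein. A second troponin C (Cluster-8110.30915) was at 52.7 ± 3.71 and 72.0 ± 5.98 FPKM (adjusted p = 0.131). The median was -0.83, or -0.57 relative to all genes (camera adjusted p = 1.33e-10, adjusted p = 0.191 with an estimated correlation), and summed FPKM was 20612 ± 1916 in dsNC and 11242 ± 1465 in dsFactin (exact permutation p = 0.1). Of the 166, 11 had a Drosophila best hit.

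Hemocyanin, the copper-based oxygen carrier of spider haemolymph, was at lower values in all 45 tested transcripts. Of the 45, 2 were positive after median-ratio rescaling, 1 with quantile normalization, 1 at pseudocounts 0.1 and 0.01, 4 with voom and 1 to 2 with a library left out. Hemocyanin subunit 3 (Cluster-8110.39244) was at 1396 ± 120 and 756 ± 103 FPKM (adjusted p = 0.0679) and the G chain (Cluster-8110.34170) at 46.5 ± 0.984 and 28.2 ± 3.05 FPKM (adjusted p = 0.0688). Summed, the family held 7.16% of FPKM in dsNC and 4.43% in dsFactin (80713 ± 8500 and 49346 ± 5189 FPKM, exact permutation p = 0.1). In limma 0 members passed over all genes and 27 had an unadjusted p under 0.05, 12 passed with voom, and 0 rose and 27 fell adjusted over the list alone. The median was -0.69, or -0.42 relative to all genes, and -0.36 after median-ratio rescaling (camera adjusted p = 1.1e-10, adjusted p = 0.435 with an estimated correlation).

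Yolk and egg genes were higher as a list but split within it. Of 58 members, 1 rose and 1 fell over all genes, and 15 rose and 5 fell adjusted over the list alone. Vitellogenin-1 rose as above, while a vitellogenin-2 hit (Cluster-14054.0) went from 2.83, 4.34 and 3.49 FPKM in dsNC to 0 in all 3 dsFactin libraries (adjusted p = 0.0314). Another vitellogenin-2 (Cluster-8110.23755) was at 0.883 ± 0.130 and 45.7 ± 42.8 FPKM (adjusted p = 0.0522) and chorion peroxidase-like (Cluster-8110.18954), an eggshell enzyme, at 3.08 ± 0.603 and 0.167 ± 0.211 FPKM (adjusted p = 0.0522). The list median was 0.08, or 0.35 relative to all genes (camera adjusted p = 6.08e-06, adjusted p = 0.144 with an estimated correlation). It was 0.0541 to 0.276 with 1 library left out and 0.61 at a mean of at least 5 FPKM.

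Detoxification genes, cytochrome P450s and conjugating and export proteins that clear foreign compounds, were higher as a list. Of 350 members, 2 rose and 1 fell over all genes, and 16 rose and 8 fell adjusted over the list alone. Cytochrome P450 4C1 rose from 28.1 ± 3.29 to 70.7 ± 5.42 FPKM and another P450 (Cluster-8110.23499) from 109 ± 4.12 to 197 ± 15.3 FPKM, while P450 4c3 (Cluster-8110.44551) differed by a log2 of -2.04 ± 0.25 (SE). A sulfotransferase 1C4-like gene (Cluster-8110.29514) was at 13.1 ± 0.458 and 5.16 ± 1.09 FPKM (adjusted p = 0.0536). The median was 0.11, or 0.38 relative to all genes (camera adjusted p = 1.1e-10, adjusted p = 0.0557 with an estimated correlation). Without a filter on low values the median was -0.0228. The calls of the cuticle, muscle, hemocyanin, yolk and detoxification lists held in all 18 settings with the preset correlation.

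Digestive enzymes, heat shock proteins and silk genes passed camera as higher than other genes, with members in both directions. Of 278 digestive genes, 0 rose and 1 fell over all genes, trypsin-1 (Cluster-8110.27190) from 3.94 ± 0.777 to 0.187 ± 0.185 FPKM, and 26 rose and 13 fell adjusted over the list alone. Chymotrypsinogen B (Cluster-8110.29553) was at 7.98 ± 1.71 and 21.8 ± 2.67 FPKM (adjusted p = 0.0536). The digestive median of -0.12 and mean of -0.20 were negative although the test pointed up (camera adjusted p = 0.00168, adjusted p = 0.191 with an estimated correlation). The digestive median was 0.15 relative to all genes, and 0.12 after median-ratio rescaling. The call was lost in 2 of 18 other settings, with quantile normalization and without a filter (highest adjusted p = 0.232). Of 129 heat shock and chaperone genes, 0 rose and 1 fell over all genes, a thioredoxin domain-containing protein (Cluster-8110.35405, log2 -1.42) that is not a heat shock protein, and 1 rose and 2 fell adjusted over the list alone. Small heat shock hits to lethal(2)essential for life were at 79.4 ± 3.82 and 365 ± 200 FPKM (Cluster-8110.30745, adjusted p = 0.0725), and heat shock protein 27 (Cluster-8110.30438) at 175 ± 7.60 and 98.8 ± 15.3 FPKM (adjusted p = 0.0661). The heat shock median of -0.07 and mean of -0.04 were again negative under a test that pointed up (camera adjusted p = 0.0217, adjusted p = 0.611 with an estimated correlation). That median was 0.20 relative to all genes and 0.22 after median-ratio rescaling. The call was lost in 6 of the 18 settings (adjusted p from 5.6e-06 to 0.665). These were no filter (adjusted p = 0.665), a mean of at least 5 FPKM (adjusted p = 0.128), quantile normalization (adjusted p = 0.300) and array weights (adjusted p = 0.0648). The others were leaving out dsNC replicate 3 (adjusted p = 0.0563) or dsFactin replicate 3 (adjusted p = 0.232). Of 42 silk genes 0 passed in limma, with 7 at an unadjusted p under 0.05, 0 with voom, and 0 rose and 0 fell adjusted over the list alone. The silk-constituting element SpiCE-CMa6 (Cluster-8110.34262) was at 481 ± 30.4 and 655 ± 55.2 FPKM (adjusted p = 0.138), and an aciniform spidroin (Cluster-8110.31410) was at 96.0, 2.69 and 5.10 FPKM in dsNC and 0, 0.720 and 0.250 FPKM in dsFactin. The silk median was 0.01 and its mean -0.13 under a test that pointed up (camera adjusted p = 0.0101, adjusted p = 0.435 with an estimated correlation), and 0.28 relative to all genes. The call was lost in 4 of the 18 settings (adjusted p from 0.000504 to 0.810). These were quantile normalization (adjusted p = 0.810), a mean of at least 5 FPKM (adjusted p = 0.190), and leaving out dsFactin replicate 2 (adjusted p = 0.0548) or 3 (adjusted p = 0.111).

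The Hippo signalling list, the kinase cascade that restrains the growth coactivator Yorkie, was lower than other genes by a small margin with camera's preset correlation, but not with an estimated correlation (adjusted p = 0.611 with an estimated correlation) or after median-ratio rescaling. The Yorkie homologue YAP1-A-like (Cluster-8110.35150) was at 28.2 ± 3.57 and 18.9 ± 2.65 FPKM (adjusted p = 0.149), its DNA-binding partner TEF-1-like (Cluster-8110.35143) at 6.35 ± 0.351 and 3.77 ± 0.716 FPKM (adjusted p = 0.140), and the kinase LATS1-like (Cluster-8110.33359) at 9.44 ± 0.732 and 5.92 ± 1.15 FPKM (adjusted p = 0.148). Upstream, four-jointed (Cluster-8110.25811) was at 4.37 ± 0.709 and 1.52 ± 0.259 FPKM (adjusted p = 0.0770), and a protocadherin Fat 4 hit (Cluster-8110.8407) at 2.38 ± 1.27 FPKM in dsNC and listed at 0 in dsFactin (adjusted p = 0.0729). Merlin-like (Cluster-8110.43773) differed by -0.31 ± 0.20, salvador (Cluster-8110.27681) by -0.22 ± 0.24 and MOB kinase activator 1B (Cluster-8110.38364) by 0.03 ± 0.14 on the log2 scale (SE). The positive members of the list with the smallest adjusted p were 14-3-3 zeta-like (Cluster-8110.34204), at 119 ± 7.16 and 199 ± 48.6 FPKM (adjusted p = 0.121), and crumbs-like (Cluster-8110.5597, log2 0.57 ± 0.54). YAP, TEF-1, LATS1, merlin, salvador and MOB were picked for their place in the pathway after their values were seen.

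Of the 62 Hippo genes tested, 0 passed over all genes in limma, 19 had an unadjusted p under 0.05 and 3 passed with voom. Among all 53182 tested genes, 10270 had an unadjusted p under 0.05 and 1162 passed with voom. Adjusted over the list alone, 0 rose and 2 fell, Fat 4 and four-jointed. All 3 dsFactin libraries lay below dsNC for 33 of 62 and above for 1, beside 21.5% and 5.98% of all tested genes. The median was -0.32, but -0.05 relative to all genes and -0.12 after median-ratio rescaling (camera adjusted p = 0.0150, adjusted p = 0.611 with an estimated correlation). The call was lost in 3 of the 18 settings (adjusted p from 0.000722 to 0.444): after median-ratio rescaling (adjusted p = 0.444), without dsFactin replicate 1 (adjusted p = 0.0611) and with a filter on mean FPKM of at least 5 (adjusted p = 0.182). A fat-like cadherin-related tumor suppressor (Cluster-8110.25323), whose name lay outside the words of the list, fell from a mean of 7.56 FPKM in dsNC, with a log2 difference of -2.58 ± 0.30 (SE, adjusted p = 0.0384, limma, chosen after its values were seen). A homolog of the same name (Cluster-8110.33676) was at 4.57 ± 0.137 and 4.44 ± 0.185 FPKM (adjusted p = 0.915). The list took in neighbours that are not Hippo components, such as a Notch hit and a heparan sulfate proteoglycan.

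**Figure D3:**
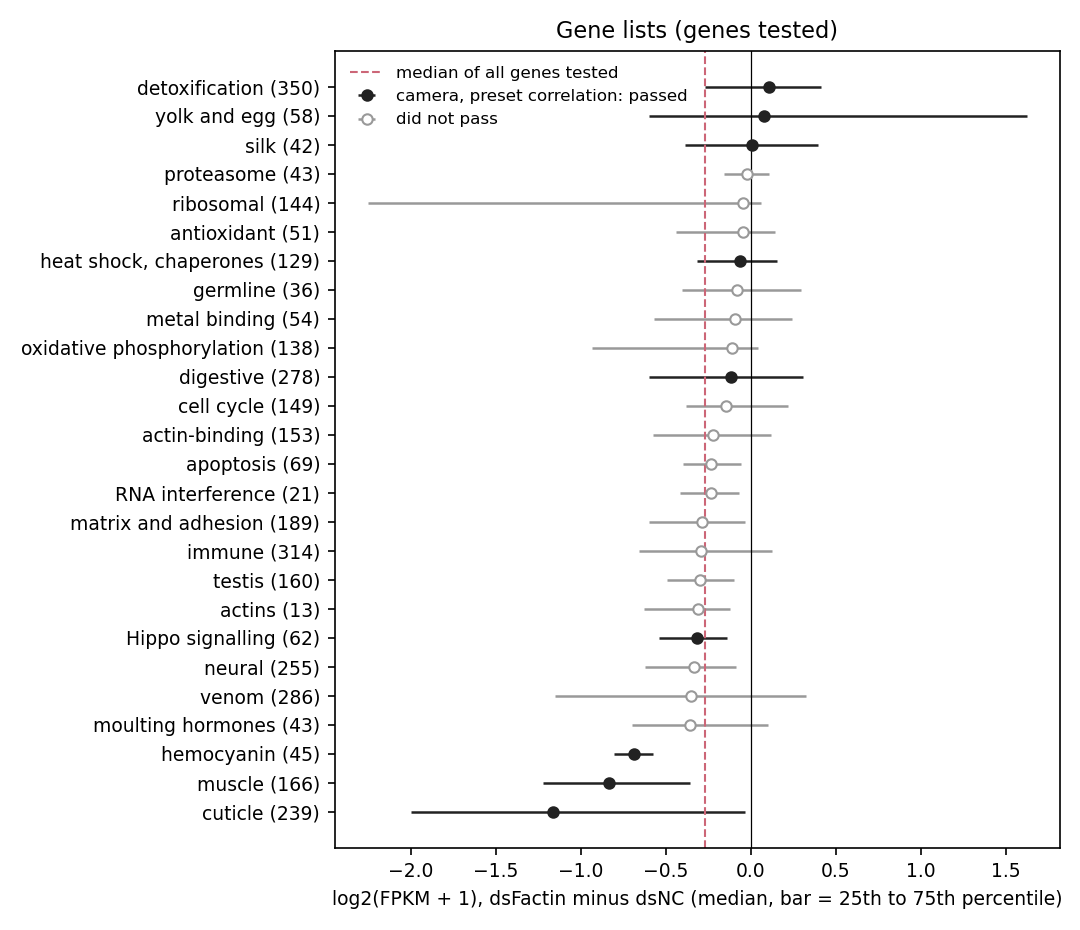
Median log2(FPKM + 1) difference, dsFactin minus dsNC, of the 26 gene lists, with bars from the 25th to the 75th percentile of members and the number of genes tested in brackets. Cuticle, muscle and hemocyanin lay farthest below the median of all genes (dashed line, -0.27) and detoxification farthest above; filled points passed camera with the preset correlation.

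The remaining lists did not pass camera at the settings fixed as the main ones, and some passed in others. Relative to all genes, the medians of lists that did not pass lay between -0.09 (moulting hormones) and 0.25 (proteasome). The metal, antioxidant, germ line, cell cycle, ribosomal, oxidative phosphorylation and proteasome lists passed as higher after median-ratio rescaling, which raises dsFactin, and germ line and cell cycle also with quantile normalization. At the deposited scaling, germ line passed as higher at a mean of at least 5 FPKM (adjusted p = 0.00159), at pseudocount 0.01 (adjusted p = 0.0412) and without dsNC replicate 2, dsFactin replicate 1 or dsFactin replicate 2 (adjusted p = 0.0487, 0.0204 and 0.0292). Proteasome passed as higher without dsNC replicate 1 or dsFactin replicate 2 (adjusted p = 0.0485 and 0.0435), and metal without Drosophila-hit genes (adjusted p = 0.0470). All of these used the preset correlation. With an estimated correlation at the main settings, camera gave germ line and proteasome each an adjusted p = 0.791. Metal-binding genes, the first line against cadmium, had a median of -0.09 and a mean of -0.32 under a test that pointed up (adjusted p = 0.0913, adjusted p = 0.324 with an estimated correlation), with 0 of 54 passing in limma, 13 at an unadjusted p under 0.05, 3 with voom, and 1 rising and 3 falling adjusted over the list alone. Transferrin (Cluster-8110.35332), an iron carrier, was at 686 ± 24.7 and 374 ± 46.7 FPKM (adjusted p = 0.0575), a venom protein similar to transferrin (Cluster-8110.34844) at 1089 ± 51.3 and 607 ± 70.2 FPKM (adjusted p = 0.0613), ferritin heavy chain A-like (Cluster-8110.30997) at 38.0 ± 2.29 and 65.1 ± 7.55 FPKM (adjusted p = 0.0681), and the zinc transporter ZIP1-like (Cluster-8110.36418) at 430 ± 30.8 and 669 ± 130 FPKM (adjusted p = 0.134). A metallothionein A transcript (Cluster-8110.15226) at 13.9, 14.2 and 1114 FPKM in dsNC and 0 in dsFactin had a Drosophila best hit. Antioxidant genes had a median of -0.05 (adjusted p = 0.201), with 0 of 51 passing, 14 at an unadjusted p under 0.05, 4 with voom, and 3 rising and 2 falling adjusted over the list alone. Glutathione synthetase-like (Cluster-8110.41054) differed by a log2 of 1.04 ± 0.20 (SE, adjusted p = 0.0784). Peroxidasin hits differed by 1.88 ± 0.37 (Cluster-8110.37950, adjusted p = 0.0800) and -1.35 ± 0.31 (Cluster-8110.38963, adjusted p = 0.0988).

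Of 314 immune genes, 0 rose and 2 fell over all genes, a chymotrypsin inhibitor (Cluster-8110.2963, log2 -2.53) and phenoloxidase-activating enzyme (Cluster-8110.40270, log2 -1.32), a trigger of melanization, and 6 rose and 24 fell adjusted over the list alone (median -0.29, adjusted p = 0.926). Positive immune members were serpin B3-like (Cluster-8110.29794, log2 1.74, adjusted p = 0.0803) and a multiple coagulation factor deficiency protein 2 homolog (Cluster-8110.33054, log2 1.85, adjusted p = 0.0827). Of 153 actin-binding genes, 0 rose and 4 fell over all genes, and 4 rose and 12 fell adjusted over the list alone (median -0.23, adjusted p = 0.926). The 4 were 3 transforming growth factor-beta-induced ig-h3 transcripts (Cluster-8110.37712, Cluster-8110.36223 and Cluster-8110.42712) and periostin-like (Cluster-8110.36517), matrix proteins taken in by the letters "formin" in "transforming". Of the 80 members without such a match, 0 passed, and 0 rose and 0 fell adjusted over the list alone (median -0.23, adjusted p = 0.890). Of 189 matrix and adhesion genes, 1 rose and 2 fell over all genes, papilin and Ig-like and fibronectin type-III proteins (Cluster-8110.37384, log2 -1.22 and Cluster-8110.38206, log2 -1.14), and 6 rose and 15 fell adjusted over the list alone (median -0.29, adjusted p = 0.338).

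Of 286 venom genes, 2 rose and 5 fell over all genes, and 30 rose and 31 fell adjusted over the list alone (median -0.35, adjusted p = 0.233). The 2 that rose were U3-aranetoxin, from 0.810 ± 0.615 to 8.44 ± 1.79 FPKM, and the nascent polypeptide-associated complex hit (Cluster-8110.50450). The latter is also on the muscle list, and its name is not that of a toxin. A more abundant U3-aranetoxin-like gene (Cluster-8110.26790, chosen after its values were seen) fell from 98.0 ± 7.66 to 42.4 ± 7.66 FPKM. A venom protease-like gene (Cluster-8110.29269, log2 -2.96) and a U-scoloptoxin hit (Cluster-8110.29907, log2 -2.41) fell. Of 160 testis and sperm genes, 0 rose and 3 fell over all genes, and 0 rose and 6 fell adjusted over the list alone (median -0.30, adjusted p = 0.179). The list passed as lower without dsFactin replicate 3 (adjusted p = 0.00191) and without a filter (adjusted p = 0.0498). The 3 were outer dense fiber protein 1 (Cluster-6116.0, 10.4 ± 3.10 FPKM in dsNC), the 1 gene with a Drosophila best hit among the 264, and protamine-like genes with spider best hits (Cluster-8110.48079 at 14.8, 5.07 and 6.54 FPKM and Cluster-8110.14737 at 14.3, 4.61 and 15.3 FPKM in dsNC), sperm proteins that were all listed at 0 in dsFactin. An axonemal dynein heavy chain 7 (Cluster-8110.34192) of the testis and sperm list was at 45.9 ± 3.28 and 194 ± 136 FPKM (adjusted p = 0.111). Of 255 nervous system genes, 1 rose and 0 fell over all genes, acetylcholine-binding protein 5, and 3 rose and 3 fell adjusted over the list alone (median -0.33, adjusted p = 0.0937). The list passed as lower without dsNC replicate 3 (adjusted p = 0.0328), without dsFactin replicate 1 (adjusted p = 0.0419) and with voom (adjusted p = 0.0210). With an estimated correlation at the main settings, camera gave the nervous system list an adjusted p = 0.791 and the testis and sperm list 0.893.

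In the lists with 0 passing genes over all genes and 0 rising or falling adjusted over the list alone, germ line genes had a median of -0.08 (adjusted p = 0.0698, 8 of 36 at an unadjusted p under 0.05, 0 with voom), apoptosis -0.23 (adjusted p = 0.544, 14 of 69, 0 with voom) and cell cycle -0.15 (adjusted p = 0.233, 37 of 149, 3 with voom). The counts in this paragraph stand beside 10270 of 53182 tested genes at an unadjusted p under 0.05 and 1162 with voom. The germ line median changed sign with the setting. It was 0.0205 without dsNC replicate 2, 0.11 after median-ratio rescaling, 0.21 with quantile normalization and 0.38 at a mean of at least 5 FPKM. Cyclin B-like (Cluster-8110.29723), a mitotic cyclin, was at 41.6 ± 6.96 and 103 ± 31.9 FPKM (adjusted p = 0.0784). A cell division control protein 42 homolog (Cluster-8110.31608) was at 7.18 ± 0.916 and 2.41 ± 0.631 FPKM (adjusted p = 0.0628). RNA interference genes had a median of -0.24 (adjusted p = 0.926, 1 of 21, 1 with voom), proteasome genes -0.02 (adjusted p = 0.112, 3 of 43, 0 with voom) and moulting hormone genes -0.36 (adjusted p = 0.825, 12 of 43, 2 with voom). Ecdysone receptor (Cluster-8110.35819) was at 32.1 ± 2.28 and 16.9 ± 3.19 FPKM (adjusted p = 0.0742) and its partner ultraspiracle (Cluster-8110.35111) at 6.77 ± 1.47 and 2.85 ± 0.661 FPKM (adjusted p = 0.0973). Juvenile hormone acid methyltransferase-3 (Cluster-8110.40186) was at 43.5 ± 5.08 and 64.5 ± 6.09 FPKM (adjusted p = 0.112). Ribosomal genes had a median of -0.04 (adjusted p = 0.825, 32 of 144, 0 with voom) and oxidative phosphorylation genes -0.11 (adjusted p = 0.840, 26 of 138, 3 with voom). Of these, 49 ribosomal and 27 oxidative phosphorylation genes had a Drosophila best hit, and the other 95 and 111 had medians of 0.02 and -0.03. The calls of both lists depended on the setting. With Drosophila-hit genes left out, the ribosomal list passed as higher (adjusted p = 9.88e-05) and the oxidative phosphorylation list did not pass (adjusted p = 0.122). Both passed as higher after median-ratio rescaling (adjusted p = 0.0249 and 0.00860) and as lower with quantile normalization (adjusted p = 3.1e-05 and 2.72e-05). These calls used the preset correlation. With an estimated correlation, run only at the main settings with all members, camera gave both lists an adjusted p = 0.945.

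Among annotation terms, 7 of 6340 passed Fisher's exact test, 4 in the higher and 3 in the lower genes. With the replicate block 0 terms passed, and 17 passed at a mean of at least 5 FPKM. Lipid transporter activity covered 5 of the 20 higher genes with a term, from 35 in the background (adjusted p = 2.42e-06), the lipoprotein amino terminal region 4 from 23 (adjusted p = 3.6e-05), lipid transport 5 from 101 (adjusted p = 0.000149) and the vitellinogen open beta-sheet 3 from 15 (adjusted p = 0.000756). In the 77 lower genes with a term, the GMC oxidoreductase family covered 5 from 26 (adjusted p = 0.000149) and, by its other domain, 4 from 29 (adjusted p = 0.00718), and CH-OH oxidoreductase activity 5 from 39 (adjusted p = 0.000829). Fisher's test counted each assembled cluster as a separate gene, so pieces of the same gene would make these p-values too small. Terms can also share clusters, so the 7 are not separate findings. Glucose dehydrogenase-like genes of the GMC family fell, such as Cluster-8110.33330 from 30.3 ± 8.87 to 0.0133 ± 0.0115 FPKM and Cluster-8110.36297 from 20.2 ± 5.20 to 0.0167 ± 0.0289 FPKM (SD, n = 3, chosen after their values were seen).

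The first principal component, 40.2% of the variance, separated the groups without overlap. It placed dsNC replicates 1 to 3 at -62.7, -68.2 and -81.3 and dsFactin replicates 1 to 3 at 87.2, -27.7 and 153, and the second, 23.9%, set dsFactin replicate 2 apart at -144. Across genes, dsFactin replicate 2 correlated with dsNC replicate 3 at r = 0.880 and with dsFactin replicates 1 and 3 at r = 0.856 and 0.832, while dsFactin replicates 1 and 3 correlated at r = 0.916 (Pearson, genes are not independent replicates). Genes with a Drosophila best hit were unevenly spread: their summed FPKM was 745, 2390 and 13922 in dsNC replicates 1 to 3 and 221, 444 and 386 in dsFactin replicates 1 to 3 (exact permutation p = 0.1). Of 2134 such genes, 648, 1418 and 2089 were above 0 in dsNC and 71, 74 and 83 in dsFactin. Without them 269 genes passed, 263 of which were among the 264, an alternative added after seeing the data. Only 211 of these genes had been tested and 1 was among the 264, so their removal could change few calls. Fly transcripts without such a best hit would remain.

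**Figure D4:**
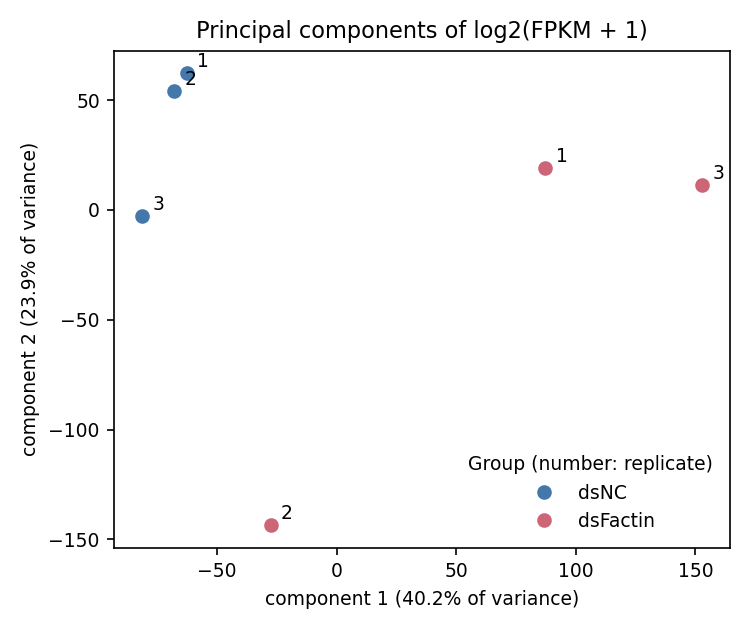
First and second principal components of log2(FPKM + 1) for the 6 libraries, numbered by replicate, with dsNC in blue and dsFactin in red. The dsNC libraries lay together at the left, and dsFactin replicate 2 lay apart from dsFactin replicates 1 and 3 on both components.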

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

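Chosen after seeing the data were voom, the Drosophila-hit removal, the filter taken again with a library left out, the shortened actin-binding list, and for lists and actins the mean of at least 5 FPKM, no filter, pseudocount 0.01, rescaling to an equal sum, no trend and array weights, as was quantile normalization for lists. Keeping the tested genes fixed when a library was left out was chosen after the counts without this had been seen. The count of changed genes, 264, was 114 at pseudocount 0.01, 117 without a filter, 781 at a mean of at least 5 FPKM, 115 after median-ratio rescaling, 174 without trend, 702 with array weights and 1162 with voom, and the cause was not tested. It was 392 at pseudocount 0.1, 206 rescaled to an equal sum, 243 with quantile normalization, 253 with a 2-fold limit and 269 without Drosophila hits. All 264 kept their sign wherever tested. Since their groups did not overlap, this was fixed beforehand except where a scaling or voom changed values between libraries. Leaving out 1 library gave 33 to 1297 genes. With the filter taken again, when 166 to 252 of the 264 were tested, it gave 12, 6 and 20 without dsNC replicates 1 to 3 and 60, 1931 and 126 without dsFactin replicates 1 to 3. With the replicate block 17 passed and 0 terms. Same-numbered libraries deviated with correlations of 0.0994, -0.108 and -0.153, and different-numbered ones with -0.140 to 0.229. These values show no pairing by number but cannot decide whether the samples were paired. The replicate block left 9 lists called. It ended 33 calls among the 128 named genes, most of which had no call to lose. The summed actin difference of -0.48 was -0.15 after median-ratio rescaling. No actin transcript passed (0), but 2 at a mean of at least 5 FPKM, 2 with voom and 1 with array weights. The log2 change of Cluster-8110.34480 turned to 0.0151 after median-ratio rescaling. After median-ratio rescaling and quantile normalization the log2 change of Cluster-8110.22599 was 0.0136 and 0.13, the log2 change of Cluster-8110.42116 0.13 and 0.15, and the log2 change of Cluster-8110.23246 0.15 and 0.15, as these scalings raise dsFactin against dsNC. Lists called numbered 9, but 15 after median-ratio rescaling, 0 with an estimated correlation, 24 with fry in either direction and 6 with directional fry, 4 of them among the 9, and 7 to 11 in the other settings with the preset correlation. Directional fry pointed down for heat shock (adjusted p = 0.616) and digestive genes (adjusted p = 0.756), since it does not compare with other genes. The heat shock median (median log2 of list heat_shock) became 0.22 after median-ratio rescaling, 0.0253 at a mean of at least 5 FPKM, 0.0420 with quantile normalization and -0.0914 to 0.00405 with 1 library left out. In the same order the digestive median (median log2 of list digestive) became 0.12, 0.0679 and 0.0683. The silk median (median log2 of list silk) was -0.0458 without a filter, -0.0306 with array weights and -0.0532 to 0.14 with 1 library left out, and the detoxification median (median log2 of list detox) -0.0228 without a filter. Terms numbered 7, and 17 at a mean of at least 5 FPKM. The recovered depth limits genes near or under 0.276 FPKM.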

Other observations

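Egg-related transcripts differed widely between single libraries, in genes picked after their values were seen. Tubuliform spidroin (Cluster-8110.26210), the silk of egg cases, was at 3.45, 0.530 and 0.740 FPKM in dsNC replicates 1 to 3 and at 198, 1.26 and 5284 FPKM in dsFactin replicates 1 to 3. A vitellogenin-3 transcript (Cluster-8110.36334) was at 247, 264 and 827 FPKM in dsNC and 153, 2306 and 14.1 FPKM in dsFactin, while another (Cluster-8110.35019) was at 3793, 4126 and 4336 FPKM in dsNC and 4156, 5173 and 6022 FPKM in dsFactin. Vitellogenin receptor-1 (Cluster-8110.43357), which takes yolk into the oocyte, was at 11.1, 9.84 and 17.7 FPKM in dsNC and 60.2, 49.0 and 118 FPKM in dsFactin (adjusted p = 0.0586, limma).

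Further single genes that passed were also named after their values were seen. Of the terms tested, fatty acid elongase activity did not pass (2 of 30 genes, adjusted p = 1). Hemolectin (Cluster-8110.35110), a clotting protein of blood cells, fell from 75.9 ± 4.71 to 40.5 ± 0.811 FPKM and hemocyte transglutaminase (Cluster-8110.31062), which cross-links clots, from 26.3 ± 2.04 to 12.9 ± 0.258 FPKM (SD, n = 3). Elongases of very long chain fatty acids fell (Cluster-8110.25053, log2 -3.54 and Cluster-8110.33497, log2 -2.37), while microsomal triglyceride transfer protein (Cluster-8110.38967), which loads lipid onto apolipoprotein B, rose by a log2 of 1.15 ± 0.14 (SE). A long-chain fatty acid ligase (Cluster-8110.33261) rose from 122 ± 10.7 to 249 ± 31.1 FPKM and a glucose transporter (Cluster-8110.37198) from 31.5 ± 2.73 to 61.2 ± 2.87 FPKM.

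The tests of explanations that follow were all written down after the results they measure had been seen.

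Genes with a Drosophila best hit were far more abundant in dsNC than in dsFactin. A lower sequencing depth in dsFactin is argued against, since mean recovered depth in dsFactin was 1.02 times that in dsNC. Depth cannot show whether part of the RNA was lost before sequencing. Genes above 0 averaged 60027 in dsNC and 52404 in dsFactin (exact permutation p = 0.1, the smallest possible). Fly RNA may be the source of these transcripts: of 51 ribosomal proteins with a Drosophila-hit transcript in the table, 86.3% also had a transcript with another best hit, as a separate set beside the spider's own would give. What made the groups differ is not shown by this. Whether feeding, handling or the injected RNA set this apart stays open, with an exact permutation p of 0.1 for the summed FPKM, the smallest that 3 libraries against 3 allow.

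Several cuticle transcripts went to near 0 in dsFactin while vitellogenin-1 appeared. The scalings tried do not account for these genes: the median change of the 23 cuticle genes that passed was -3.82 and at most -3.61 under another scaling, and vitellogenin-1 stayed between 8.36 and 8.68. These were picked by their large change in the same data, so the check says nothing on the whole list. For all 239 tested cuticle genes the median was -0.89 after median-ratio rescaling and -1.02 with quantile normalization. Random loss of transcripts is argued against by the whole cuticle list: of 207 members high enough to fall 4-fold, 27.5, 48.3 and 32.4% did so in dsFactin replicates 1 to 3, against 5.90, 3.97 and 8.21% of other genes matched for dsNC level. A difference in sex, moult stage or reproductive state between the individuals may underlie both. It cannot be told apart from an effect of the injected RNA, since no label gives sex or stage. The testis and sperm list had a median of only -0.30, or -0.03 relative to all genes, although protamine-like genes were at 0. The biological explanation by the design, the injected RNA, stays open too.

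The 7 abundant actins differed in their change between groups, from -1.26 for actin-87E to 0.15. A factor per library, as in FPKM, moves all 7 alike, and this is argued against as the whole cause: the SD of their log2 changes was 0.67 beside a root mean square SE of 0.23. Whether actin-87E and the A3a-like transcript moved with muscle content was not decided. Of the muscle list, 22.9% lay at or below the change of actin-87E and 31.3% at or below that of the A3a-like transcript. That list was wide (25th to 75th percentile -1.22 to -0.36), so a moderate fall of any cause would lie within it. Loss of a targeted transcript stays open as well: the lowest actin change was -1.26, above the 5th percentile of the muscle list at -1.94, and which transcript was targeted is not given in the sources used here.

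The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 264 genes and the highest of the others 0, so 1 of the 10 splits reached it. For gene lists the real split gave 9 and the highest other 11, and 3 of the 10 splits gave at least as many. For annotation terms the real split gave 7 and the highest other 0, 1 of the 10, which was fixed by the 0 genes called in the other splits and is no separate check.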
